A study of Mus musculus with 13 samples.

How the data were processed

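Leg muscle RNA of mdx mice, which carry a mutation in the dystrophin gene and are a model of Duchenne muscular dystrophy, and of control mice was measured on Affymetrix oligonucleotide arrays. The labels give 3 control and 3 mdx samples at day 7, 3 control and 3 mdx samples at day 14 and 1 control sample at day 23. They do not say that the samples came from separate animals, so the p-values measure the spread between these samples. Sex, strain and the muscle taken are not given in the sources used here.

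The deposited values are intensities on a linear scale, with 1 value per probe set and array, for 12488 probe sets. Per the labels, the authors followed the standard protocol of the array's maker; the software that summarised the probes is not given in the sources used here. The mean of each array after trimming 2% of the probe sets from each end lay between 1500.69 and 1501.09, so the deposited values had been brought to a common target on each array. No value was below 0 and no 2 arrays held identical values. The number of arrays limits the precision, and no read depth applies.

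The array medians still differed 1.47-fold, above the limit of 1.25 that had been set for using the values as deposited. The 13 arrays were therefore quantile-normalised over 12422 probe sets, after leaving out 66 probe sets for controls. A pseudocount of 62.15, equal to 10% of the median of all values, was added before taking log2, so fold changes of dim probe sets are understated. A probe set was tested if at least 3 of the 12 arrays of the replicated groups exceeded 621, the median of the normalised values, which left 7140. Gene names came from the platform annotation. Among the 12422 probe sets, 10833 had 1 gene symbol, 396 had several and 1193 had none listed, and only those with 1 symbol are named. No genome build is named by the sources used here, and no coordinates are given.

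All 12 replicated arrays entered a single fit with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with intensity and 8 residual degrees of freedom. The contrasts were mdx against control at each age, the difference between these effects, and day 14 against day 7 in each genotype. P-values were adjusted by the method of Benjamini and Hochberg over 7140 probe sets, with a threshold of 0.05. Level values in the text are normalised intensities as mean ± SD, and log2 differences carry the standard error of the fit.

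Gene lists were tested with camera at a preset correlation of 0.01, over 5466 genes represented by their brightest probe set, and again with a correlation estimated from the residuals. P-values were adjusted over 26 lists within each contrast. The lists were the dystrophin complex, myogenic regulators and satellite cells, embryonic and neonatal muscle isoforms, imprinted growth genes, adult fast fibre genes, slow fibre genes, extracellular matrix, macrophage and myeloid, T and B lymphocytes, antigen presentation, chemokines and cytokines, complement, interferon response, neutrophil and marrow, erythroid, adipocyte, bone and cartilage, endothelial, nerve and Schwann cell, epidermis, cell cycle, oxidative phosphorylation, glycolysis and glycogen, fatty acid oxidation, proteolysis and atrophy, and immediate early genes. The single day 23 array had no test; its list medians were placed among 10000 random lists of the same size matched on mean intensity in 10 bins.

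The groups, lists, tests, the rule for named genes and most alternatives were set before the data were examined. The rule named the 10 largest rises and falls past the threshold with non-overlapping groups in each 2-group contrast, with 1 probe set per gene, the one with the smallest adjusted p, the 5 largest in each direction for the difference of the mdx effects, and Dmd. From each list past the threshold it took up to 4 members with the smallest adjusted p in the direction of the list, and from other lists up to 2 of the brightest members. For day 23 it took the 5 largest rises and falls against the day 14 control mean among probe sets whose higher side exceeded the 75th percentile of all values. Alternatives covered the pseudocount, filter, scaling, variance model, arrays in the fit, threshold, a replicate block and leaving out each array. The fit was tested on simulated data with 200 of 7140 probe sets changed. For mdx against control at day 7 it recovered 57% of changes of 1 and 92% of changes of 2 on the log2 scale, with 7 false calls among 156. For mdx against control at day 14 it recovered 54% and 94%, with 11 false calls among 159. For the difference of the mdx effects it recovered 22% and 86%. For day 14 against day 7 it recovered 62% and 89% in control and 66% and 96% in mdx. In the camera test on simulated data, a shift of 0.5 in 18 genes gave an adjusted p of 5.72e-07 and 0 of the other 25 lists passed. The simulated probe sets varied independently, whereas the estimated correlation within the real lists went up to 0.342. The simulation therefore could not show false list calls that arise from correlated genes. It also gave each probe set the same spread in all groups, so its rates do not cover groups that differ in spread.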

Results

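Gene expression was measured in leg muscle of control and mdx mice at day 7 and day 14, with 3 arrays per group, and in 1 control array at day 23. Totals over all probe sets ran from 22349400 on replicate 3 of mdx at day 7 to 26741300 on replicate 2 of mdx at day 14. The first principal component held 53.0% of the variance. It set the 6 day 14 arrays, with scores of 20.7 to 62.6, apart from the 6 day 7 arrays, with scores of -34.8 to -23.8, and from the day 23 array at -15.1. Replicate 2 of control at day 14 had the score of 62.6 and a mean correlation of 0.878 with the other arrays of its group, against 0.900 to 0.967 for the other 11 replicated arrays.

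**Figure D1:**
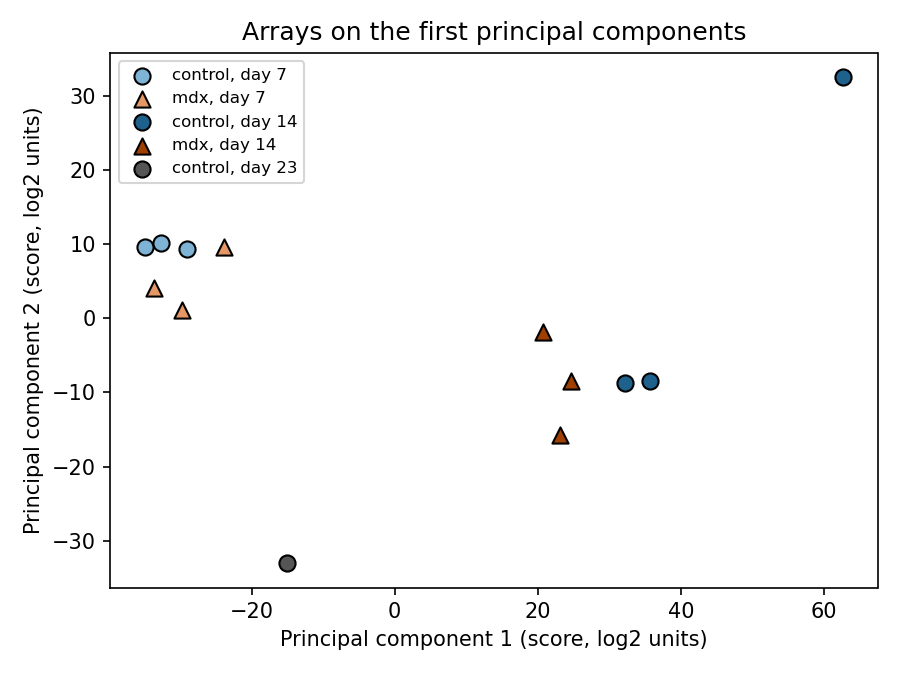
Scores of the 13 arrays on the first and second principal components of log2 normalised intensity; circles are control, triangles are mdx, and colours mark the age. The day 14 arrays lie at 20.7 to 62.6 on the horizontal axis, the day 7 arrays at -34.8 to -23.8 and the day 23 array at -15.1.

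The first comparison asked how mdx muscle differed from control muscle at day 7. Genes of neutrophils and their marrow precursors were lower in mdx. Over the 9 measured genes of that list the median log2 difference was -2.53, with a camera adjusted p of 1.07e-14 and one of 0.0205 with an estimated correlation. The latter was 0.0561 without replicate 1 of mdx, 0.130 with a replicate block and 0.0953 without the 3 arrays on which some of the brightest probe sets read low, a setting chosen after the data were seen. Ngp, a neutrophil granule protein, read 354 ± 444 (SD, n = 3) in mdx and 2341 ± 491 in control, a log2 difference of -3.14 (SE 0.62). S100a8, a calcium-binding protein abundant in neutrophils, read 1087 ± 1155 in mdx and 6858 ± 1591 in control, a log2 difference of -3.03 (SE 0.67). At day 14 S100a8 read 1223 ± 293 in control and 1375 ± 934 in mdx, near the day 7 mdx value, and 34.0 on the day 23 control array. Mmp9, a gelatinase, differed by -3.88 (SE 0.99) and Camp, the cathelicidin precursor, by -2.53 (SE 0.53). Of the 9 genes, 0 passed over all probe sets tested and 8 were lower when adjusted over the list alone. Replicate 2 of mdx had Ngp at 859, against 27.4 and 175 on the other mdx arrays and 1853 to 2835 in control.

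Bone and cartilage genes were lower in the same arrays. The median over 11 genes was -0.74 (camera adjusted p = 1.90e-10), and -1.30 to -0.57 leaving out 1 array. With an estimated correlation the adjusted p was 0.0205, up to 0.0351 leaving out 1 array, 0.130 with a replicate block and 0.0783 without the 3 arrays. Adjusted over the list alone, 6 genes were lower. Col11a1 and Col11a2, chains of a cartilage collagen, differed by -1.27 (SE 0.23) and -1.24 (SE 0.30). Acan, the cartilage proteoglycan aggrecan, differed by -1.66 (SE 0.49) and Alpl, the phosphatase of mineralising bone, by -1.52 (SE 0.45). The erythroid list had a median of -0.70 over 6 genes (camera adjusted p = 2.62e-05), with an adjusted p of 0.0803 with an estimated correlation and 3 genes lower adjusted over the list alone. Slc4a1, the anion exchanger of red cells, differed by -1.57 (SE 0.25), and Klf1, an erythroid transcription factor, by -0.92 (SE 0.28), while the globin gene Hbb-b2 differed by -0.22 (SE 0.21). After removing group means, the marrow and bone list scores correlated over the 12 arrays at r = 0.763 (permutation p = 0.0434, adjusted over 3 relations 0.0743) and rho = 0.713 (permutation p = 0.0428), and at r = 0.527 without the 2 arrays farthest from the median. Marrow and erythroid scores correlated at r = 0.591 (permutation p = 0.0495, adjusted 0.0743) and bone and erythroid scores at r = 0.498 (permutation p = 0.192), or 0.595 and 0.271 without the 2 arrays.

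**Figure D2:**
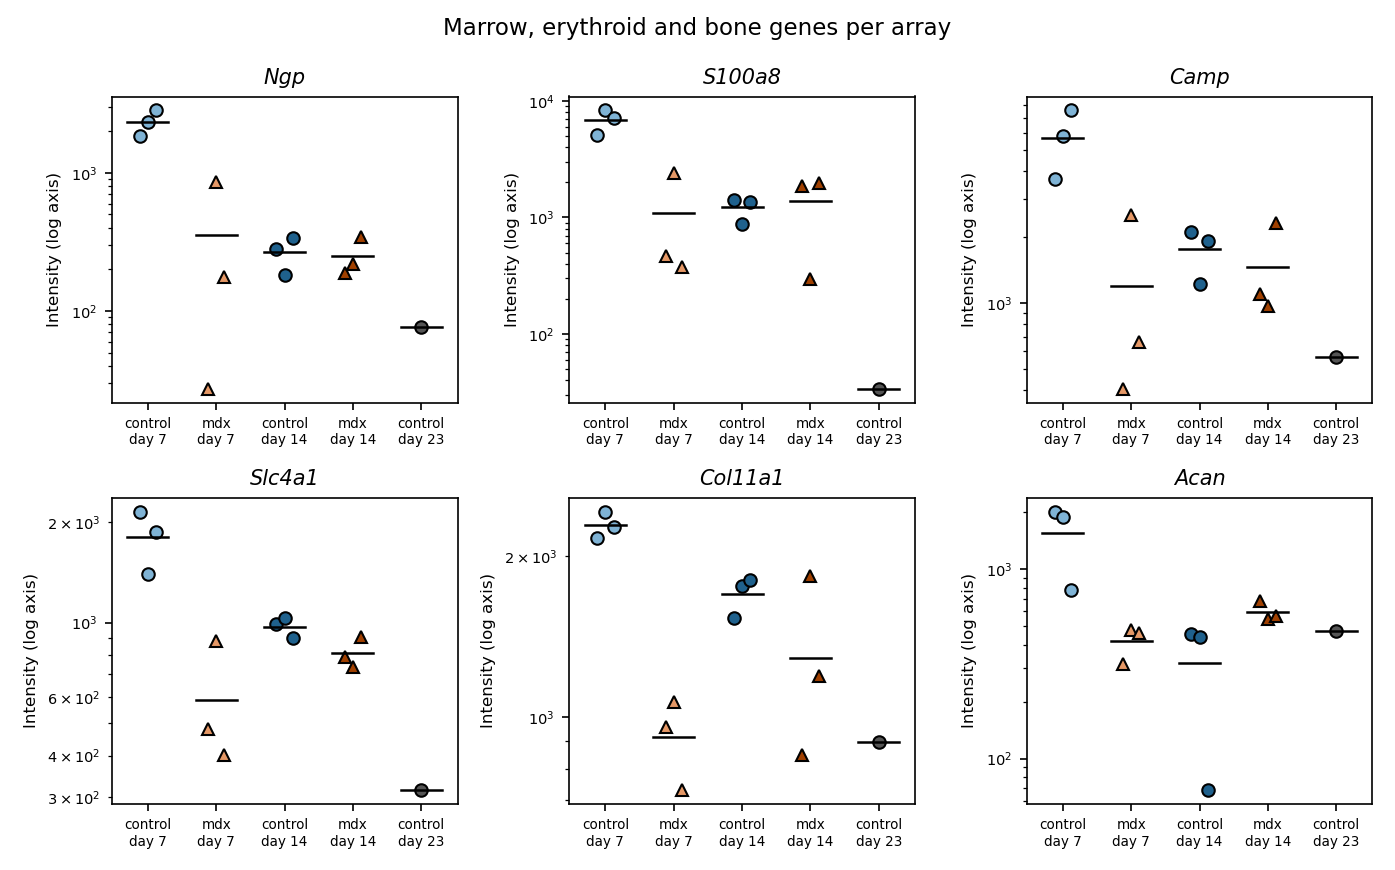
Normalised intensity on a log axis for 6 marrow, erythroid and bone genes on each of the 13 arrays, with a horizontal line at the group mean; circles are control and triangles mdx. At day 7 the control arrays of Ngp lie at 1853 to 2835 and the mdx arrays at 27.4, 175 and 859.

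Another 7 lists passed camera at day 7, and their calls were lost with an estimated correlation. Immediate early genes were higher, with a median of 0.21 (adjusted p = 0.000840, and 0.236 with an estimated correlation). In that list the nuclear receptor Nr4a1 differed by 1.34 (SE 0.32) and the transcription factor Fos by 1.38 (SE 0.46). Adipocyte genes were higher, with a median of 0.34 (adjusted p = 0.00493, and 0.236 with an estimated correlation), with the lipid desaturase Scd1 at 1.16 (SE 0.60). Cell cycle genes were lower, with a median of -0.18 (adjusted p = 0.00125, and 0.118 with an estimated correlation), with the replication helicase subunit Mcm5 at -0.39 (SE 0.20). Slow fibre genes were lower, with a median of -0.32 (adjusted p = 0.00514, and 0.350 with an estimated correlation), with slow troponin C, Tnnc1, at -0.61 (SE 0.30). Macrophage and myeloid genes were lower, with a median of -0.16 (adjusted p = 0.00546, and 0.236 with an estimated correlation), with the macrophage marker Adgre1 at -0.88 (SE 0.41). Imprinted growth genes were higher, with a median of 0.25 (adjusted p = 0.0257, and 0.236 with an estimated correlation), with Ndn at 0.32 (SE 0.20). Oxidative phosphorylation genes were higher, with a median of 0.10 (adjusted p = 0.0406, and 0.390 with an estimated correlation), with Sdha, a subunit of succinate dehydrogenase, at 0.50 (SE 0.21); with each array scaled to the same median this list's median was -0.00 and its adjusted p 0.681. The imprinted list did not pass with that scaling (adjusted p = 0.209) or with the values as deposited (adjusted p = 0.236).

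Several of these calls depended on 1 array. Without replicate 2 of mdx the immediate early list had an adjusted p of 0.250, the adipocyte list 0.0807 and the oxidative phosphorylation list 0.650. Without replicate 3 of control the slow fibre list had 0.0811, the macrophage list 0.0522 and the oxidative phosphorylation list 0.166. Without replicate 3 of mdx the macrophage list had 0.0603 and the imprinted list 0.0966. Without replicate 2 of control the imprinted list had 0.122 and the oxidative phosphorylation list 0.0712, and without replicate 1 of mdx the latter had 0.0949.

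For single probe sets limma called 0 of 7140 between mdx and control at day 7. An unadjusted p under 0.05 was reached by 258, where 357 are expected by chance, and the smallest adjusted p was 0.242. The fit used a single spread per probe set for all groups. Mean correlations within the group were 0.946 to 0.967 for the day 7 arrays and 0.878 to 0.934 for the day 14 arrays. A shared spread can therefore make p-values too large at day 7 and too small at day 14, which was not tested. Dmd, the dystrophin gene, read 621 ± 179 in mdx and 846 ± 21.4 in control, a log2 difference of -0.44 (SE 0.30, limma adjusted p = 0.998). Without replicate 2 of mdx limma called 12 probe sets, all lower in mdx. The groups did not overlap for 13.8% of probe sets, where chance gives 10%.

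The second comparison asked the same at day 14. Myh3, the embryonic myosin heavy chain, read 961 ± 158 (SD, n = 3) in mdx and 447 ± 19.1 in control, a log2 difference of 1.00 (SE 0.16, limma adjusted p = 0.0402). At day 7 Myh3 had read 4528 ± 414 in mdx and 6089 ± 842 in control, so it fell with age in both genotypes. Snx17, a sorting nexin of endosomes, was higher by 2.05 (SE 0.17, adjusted p = 0.000233), and Psmd10, an assembly chaperone of the proteasome, by 1.75 (SE 0.26, adjusted p = 0.0402). Erdr1 was lower, at 1397 ± 501 in mdx and 6611 ± 1601 in control, a log2 difference of -2.22 (SE 0.34, adjusted p = 0.0402). Dmd read 325 ± 24.2 in mdx and 868 ± 350 in control. Its log2 difference of -1.18 (SE 0.30) had an unadjusted p of 0.00163 in limma and did not pass the adjustment (adjusted p = 0.164), although the 3 mdx arrays, at 308 to 353, lay below the 3 control arrays, at 476 to 1150. Without replicate 2 of control, which had the 476, the difference in Dmd was -1.55 and passed.

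In total 6 of 7140 probe sets passed at day 14, 4 higher and 2 lower in mdx. The other 2 have no gene symbol listed, with log2 differences of 2.39 and -1.04. An unadjusted p under 0.05 was reached by 1155, against 357 expected, and the groups did not overlap for 16.3% of probe sets, where chance gives 10%. The spread shared with the day 7 arrays can make p-values at day 14 too small, since the day 14 arrays agreed less within their groups. A second probe set for Snx17 differed by -0.44 (adjusted p = 0.581), and a second for Erdr1 by -0.78 (adjusted p = 0.196). The higher value of Snx17 in mdx came with a low control value at day 14: control read 1980 ± 205 at day 7, 251 ± 36.3 at day 14 and 1870 on the day 23 array. Psmd10 likewise read 807 ± 165, 92.7 ± 27.6 and 828 in control. For Myh3 the day 23 control array read 928, near the mdx mean of 961 at day 14.

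**Figure D3:**
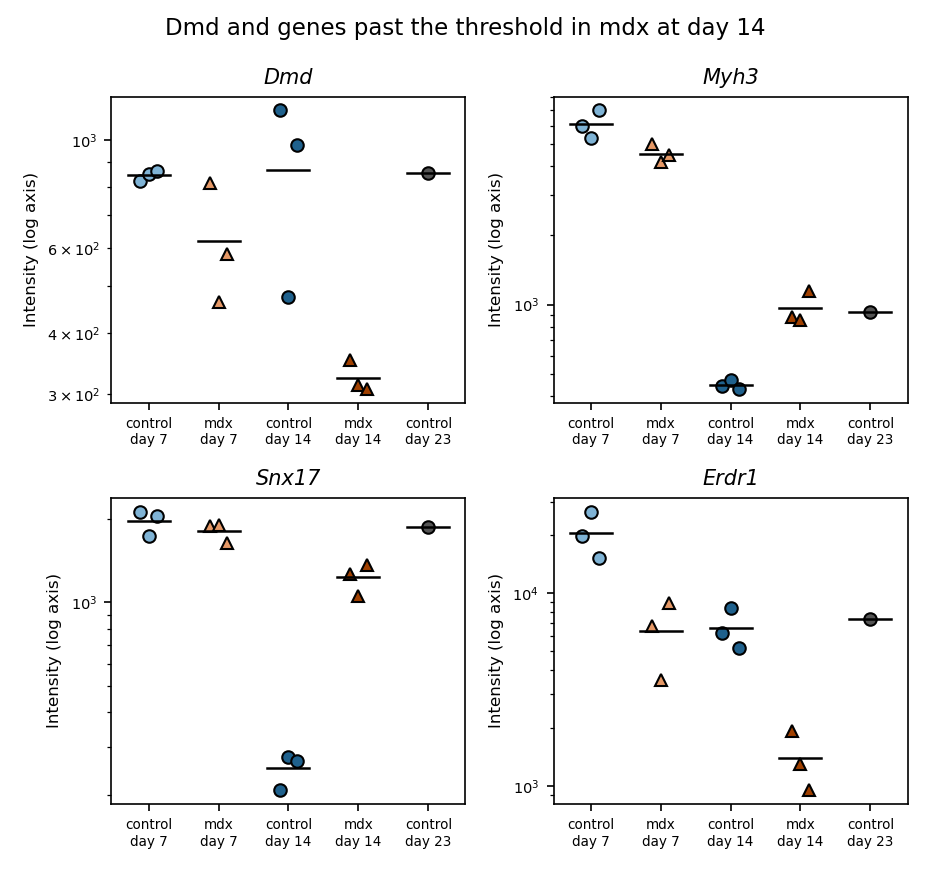
Normalised intensity on a log axis for Dmd, Myh3, Snx17 and Erdr1 on each of the 13 arrays, with a horizontal line at the group mean; circles are control and triangles mdx. At day 14 the mdx arrays of Dmd lie at 308 to 353 and the control arrays at 476 to 1150, and Snx17 in control drops to a mean of 251 at day 14 and reads 1870 at day 23.

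Of 26 gene lists 0 passed at day 14 under camera, and the smallest adjusted p with an estimated correlation was 0.862. The lists of imprinted growth genes (median 0.36), nerve and Schwann cell genes (-0.35), epidermis genes and proteolysis genes had an unadjusted p under 0.05 and an adjusted p of 0.217. The imprinted and nerve lists passed (adjusted p = 0.0361) without the 3 arrays on which some of the brightest probe sets read low, a setting chosen after the data were seen. The dystrophin complex had a median of 0.26 (adjusted p = 0.641), with Dag1, dystroglycan, at 0.18 (SE 0.13) and Cav3, muscle caveolin, at 0.36 (SE 0.20). Myogenic regulators and satellite cells had a median of 0.16 (adjusted p = 0.622). Macrophage and myeloid genes had one of 0.12 (adjusted p = 0.641), with 10 of 19 genes above 0 and 9 below. Adjusted over the list alone, 3 of the 19 were higher in mdx and 0 lower. C1qc was at -0.02 (SE 0.16), or 0.0926 with each array scaled to the same median, while Lgals3 read 531 ± 122 in mdx and 138 ± 105 in control. Adjusted over their lists alone, 1 dystrophin complex gene and 1 erythroid gene were lower. In the same way 2 embryonic and neonatal isoforms and 1 extracellular matrix gene were higher. Extracellular matrix genes had a median of -0.02 (adjusted p = 0.772), a mean of 0.07 and an upward test, with Col3a1 at 0.23 (SE 0.21). Embryonic and neonatal isoforms had a median of -0.03, a mean of 0.09 and an upward test (adjusted p = 0.772), and 1 of the 17, Myh3, passed as higher in mdx. Neutrophil and marrow genes had a median of -0.07, a mean of 0.10 and a downward test (adjusted p = 0.689), with S100a8 at -0.17 (SE 0.67), or 0.65 without replicate 2 of mdx. Bone and cartilage genes had a median of 0.12, a mean of -0.02 and a downward test (adjusted p = 0.577).

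The number of calls at day 14 depended on single arrays and settings. Without replicate 1, 2 or 3 of control it was 50, 13 or 56, without replicate 2 or 3 of mdx it was 1, and in a fit of the 6 day 14 arrays alone it was 0.

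The remaining lists passed in no comparison of mdx with control. At day 14 the adult fast fibre list had a median of -0.21 (adjusted p = 0.417), the T and B lymphocyte list -0.11 (adjusted p = 0.577), antigen presentation 0.01 with a downward test (adjusted p = 0.641), chemokines and cytokines -0.03 with a mean of 0.01 (adjusted p = 0.772) and complement -0.10 (adjusted p = 0.772). Interferon response genes had a median of 0.22 (adjusted p = 0.577), endothelial genes -0.01 with a mean of 0.01 (adjusted p = 0.772) and epidermis genes -0.42 (adjusted p = 0.217). Glycolysis and glycogen genes had a median of -0.14 (adjusted p = 0.577), fatty acid oxidation genes 0.09 with a downward test (adjusted p = 0.953) and proteolysis and atrophy genes 0.24 (adjusted p = 0.217).

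The third comparison tested whether the mdx effect differed between the ages. Snx17 was the single probe set past the threshold, with a difference of 2.17 (SE 0.24, limma adjusted p = 0.00618), of 7140 tested. The other probe set of Snx17 had a difference of -0.495 (limma adjusted p = 0.784). An unadjusted p under 0.05 was reached by 678. For Dmd the difference was -0.74 (SE 0.42, adjusted p = 0.583).

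Among the 26 lists 6 passed camera for this difference, and 0 with an estimated correlation, where the smallest adjusted p was 0.445. Neutrophil and marrow genes had a median difference of 2.33 (camera adjusted p = 0.000685), with a median change with age of -1.90 in control (adjusted p = 0.186), where 7 of 9 fell and 1 rose, and of 0.43 in mdx (adjusted p = 0.480), where 0 of 9 rose. Bone and cartilage genes had one of 0.70 (adjusted p = 0.0263), which was 0.33 to 1.09 leaving out 1 array. Their median change with age was -0.42 in control (adjusted p = 0.545) and 0.20 in mdx (adjusted p = 0.542). In these lists Mmp9 differed by 5.09 (SE 1.40) and Acan by 2.68 (SE 0.69). Acan read 68.3 on replicate 3 of control at day 14, against 441 and 454 on the other control arrays of that age. Macrophage and myeloid genes had a median of 0.42 (adjusted p = 0.0487), with the lectin Lgals3 at 2.04 (SE 0.59) and the lysozyme Lyz2 at 1.22 (SE 0.42). These 2 differences came mainly with falls in control. From day 7 to day 14 Lgals3 went from 693 to 138 in control, with 17.4 on replicate 3, and from 551 to 531 in mdx. Lyz2 went from 2079 to 1041 in control and from 1980 to 2182 in mdx, and read 1867 on the day 23 control array. Adipocyte genes had a median of -0.61 (adjusted p = 0.0240), nerve and Schwann cell genes -0.43 (adjusted p = 0.0455) with myelin basic protein, Mbp, at -0.67 (SE 0.28), and oxidative phosphorylation genes -0.12 (adjusted p = 0.0408). The last of these medians was 0.09 with each array scaled to the same median, a scaling that moved the median of all probe sets to 0.16 from 0.06. With that scaling 2 lists passed.

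The calls for the difference depended on single arrays. The count of probe sets was 0 without replicate 1 of control at day 7, 6 without replicate 2 of mdx at day 7, and 16, 2 and 4 without replicates 1, 2 and 3 of control at day 14. The count of lists was 3 without replicate 3 of control or replicate 1 of mdx at day 7, 2 without replicate 1 or 3 of control at day 14, and 1, the neutrophil and marrow list, without replicate 3 of mdx at day 14. With each of the 12 arrays left out in turn, the marrow list passed 12 times, with adjusted p-values up to 0.0177, the bone list 10 times (up to 0.0925) and the adipocyte list 10 times (up to 0.163). The oxidative phosphorylation list passed 6 times (up to 0.253), the macrophage list 4 times (up to 0.236) and the nerve list 4 times (up to 0.182).

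The fourth comparison followed control muscle from day 7 to day 14. Myh3 fell to 447 ± 19.1 (SD, n = 3) from 6089 ± 842, a log2 difference of -3.59 (SE 0.16, limma adjusted p = 8.38e-08), and Myh8, the neonatal myosin heavy chain, by -3.54 (SE 0.35). Of 17 embryonic and neonatal isoforms 9 fell and 1 rose, with a median of -0.78 (camera adjusted p = 0.00867, and 0.296 with an estimated correlation). Myl4, an atrial and embryonic myosin light chain, fell by 2.38 (SE 0.23) on its named probe set and rose by 1.04 on another. Tnnt2, cardiac troponin T, fell by 1.37 (SE 0.22). Without replicate 1 of control at day 14 this list had an adjusted p of 0.0538.

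Of 15 imprinted growth genes 9 fell and 2 rose in control, with a median of -1.37 (camera adjusted p = 0.0141, and 0.296 with an estimated correlation). Dlk1, a membrane protein of growing muscle and fat precursors, fell by 2.20 (SE 0.22), Ndn fell by 1.82 (SE 0.20) and Plagl1 fell by 2.40 (SE 0.29). Meg3 fell by 2.25 (SE 0.23) on one probe set and rose by 4.34 on another. Of 29 cell cycle genes 17 fell and 0 rose, with a median of -0.89 (camera adjusted p = 0.00107, and 0.280 with an estimated correlation). Cdk1, the mitotic kinase, fell by 1.71 (SE 0.28), Mcm7 fell by 1.68 (SE 0.22) and Cks2 fell by 2.11 (SE 0.28). Of 34 extracellular matrix genes 20 fell and 1 rose, with a median of -0.66 (camera adjusted p = 0.00803, and 0.296 with an estimated correlation). Tnc, tenascin C, fell by 1.95 (SE 0.18), Ogn fell by 2.06 (SE 0.18) and Col6a2 fell by 1.26 (SE 0.16).

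Of 52 oxidative phosphorylation genes 18 rose and 1 fell in control, with a median of 0.27 (camera adjusted p = 0.00334, and 0.296 with an estimated correlation), among them Sdha by 0.99 (SE 0.21) and Cox6b1 by 1.22 (SE 0.23). Of 18 genes of glycolysis and glycogen 7 rose and 0 fell, with a median of 0.56 (camera adjusted p = 0.00670, and 0.619 with an estimated correlation). These included Phka1, a subunit of phosphorylase kinase, at 1.29 (SE 0.31), and Ugp2, an enzyme of glycogen synthesis, at 0.78 (SE 0.16). Fatty acid oxidation genes did not pass, with a median of 0.22 (adjusted p = 0.155).

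**Figure D4:**
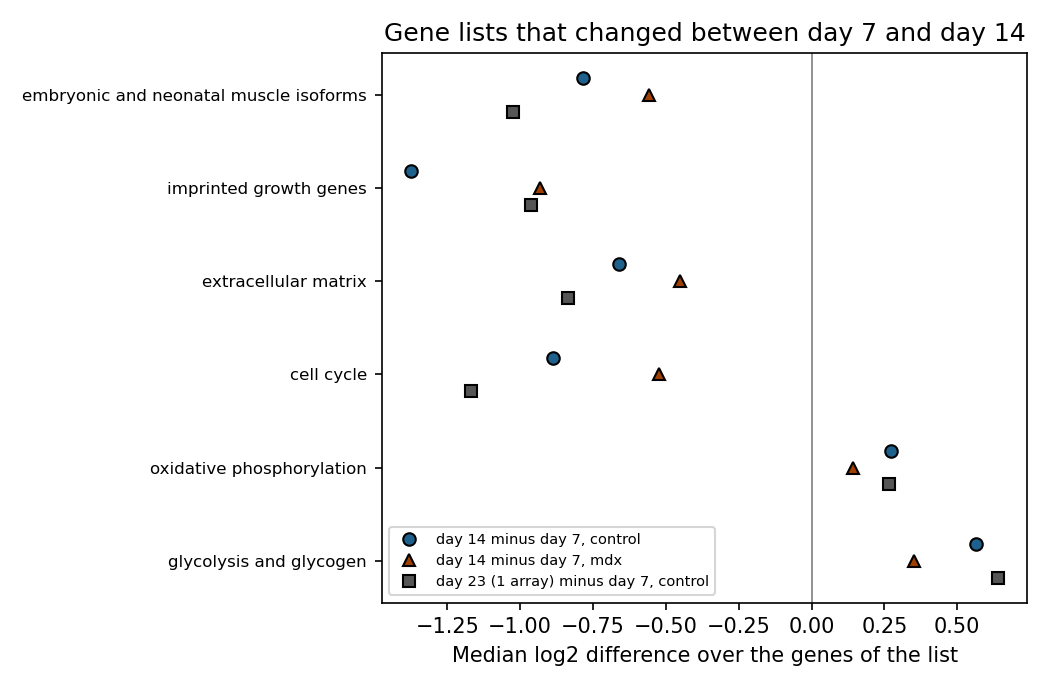
Median log2 difference from day 7, on the horizontal axis, for 6 gene lists in control at day 14 (circles), mdx at day 14 (triangles) and the single control array at day 23 (squares). Embryonic and neonatal isoforms lie at -0.78, -0.56 and -1.02, and glycolysis and glycogen genes at 0.56, 0.35 and 0.64.

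Among the other largest falls in control were Mmp9 (-5.06, SE 0.99), the linker histone H1f10 (-3.50, SE 0.28), Cks1b (-3.38, SE 0.30), the angiotensin receptor Agtr2 (-3.37, SE 0.46), Myzap (-3.27, SE 0.34), the collagenase Mmp13 (-3.25, SE 0.74), the osteoclast phosphatase Acp5 (-3.23, SE 0.75) and Col18a1 (-3.18, SE 0.25, with another of its probe sets at 0.19). At day 7 Mmp9, Mmp13 and Acp5 read 6044, 3355 and 4232 in control and 982, 522 and 898 in mdx. Whether their falls in control share a source with the marrow and bone difference at day 7 was not tested. With 1 probe set per gene, the one with the smallest adjusted p, and apart from the 4.34 of the other Meg3 probe set, the largest rises were in Rpl41 (5.79, SE 1.12), Igf2 (4.14, SE 1.05), Zfp94 (3.92, SE 0.53) and Gnas (3.29, SE 1.08, with its other probe set at -0.46), followed by Cyp2c39 (2.91), H2-T18 (2.89), Actn2 (2.64), Aopep (2.62, with its other probe set at 0.42), F2rl2 (2.56) and Ift46 (2.56, with its other probe set at 0.05). Rpl41, a ribosomal protein gene, read 149 to 1684 on the day 7 control arrays, 19498 to 29870 on those of day 14 and 718 on replicate 1 of mdx at day 14. Igf2, a fetal growth factor gene, likewise read 544 on that mdx array, against 12716 and 32480 on the other mdx arrays of day 14. Gnas, an imprinted gene for a G protein subunit, ranged from 372 to 22351 between the day 7 control arrays, with the 372 on replicate 2. That array and replicate 1 of mdx at day 14 are among those on which some of the brightest probe sets read low. Whether such low readings at day 7 account for the rises of Rpl41, Igf2 and Gnas was not tested. On the day 23 array Rpl41, Igf2, Gnas and Actn2 read 19540, 18810, 27966 and 810. Their day 14 control means were 25048, 19146, 25768 and 940. Zfp94, Cyp2c39, H2-T18 and F2rl2 read 2732, 561, 2085 and 345, between the control means of day 7 and day 14. Aopep and Ift46 read 2008 and 177, below their day 7 control means of 2501 and 234.

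In total 3408 of 7140 probe sets passed in control, 1500 higher and 1908 lower at day 14. With each array scaled to the same median the split was 1137 higher and 2709 lower, with a shift of -0.31 in the median of all probe sets, and with the values as deposited it was 1764 higher and 1764 lower. Spike-in controls, which are added to each sample, had a mean log2 deposited signal of 12.89 ± 0.30 (SD, n = 6) on the day 14 arrays, 12.23 ± 0.29 on the day 7 arrays and 12.48 on the day 23 array (exact two-sided permutation p = 0.00216, day 14 against day 7). The ratio of the 3' to the 5' Gapdh control value was 0.020 to 0.310 in control at day 7 and 0.345 to 0.535 in control at day 14. It was 0.0915 on the day 23 array, and in mdx the ages overlapped. The beta-actin ratios in control overlapped, at 0.518 to 0.809 and 0.797 to 1.17. The Gapdh ratio was at most 0.810 on the 13 arrays, so its 3' value read below its 5' value on each of them. What lowered the 3' value was not tested, so this ratio does not measure RNA quality alone. Whether RNA quality contributed to the calls was not tested. Of the calls in control 1087 had a day 23 value at least 50% of the way from the day 7 mean to the day 14 mean, a criterion added after the data were seen.

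The fifth comparison followed mdx muscle over the same days. Myh3 fell by 2.17 (SE 0.16, limma adjusted p = 1.87e-05) and Myh8 fell by 2.78 (SE 0.35). Of 17 embryonic and neonatal isoforms 8 fell, with a median of -0.56 (camera adjusted p = 0.00179, and 0.123 with an estimated correlation). Of 15 imprinted growth genes 9 fell, with a median of -0.93 (camera adjusted p = 0.00179, and 0.123 with an estimated correlation), in which Dlk1 fell by 1.98 (SE 0.22) and Ndn fell by 1.85 (SE 0.20). Of 29 cell cycle genes 12 fell, with a median of -0.53 (camera adjusted p = 0.00121, and 0.123 with an estimated correlation), and of 34 extracellular matrix genes 13 fell and 2 rose, with a median of -0.45 (camera adjusted p = 0.00231, and 0.123 with an estimated correlation).

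Of 52 oxidative phosphorylation genes 9 rose and 2 fell in mdx, with a median of 0.14 (camera adjusted p = 0.0322, and 0.633 with an estimated correlation). Cycs, cytochrome c, rose by 1.27 (SE 0.29) and Cox7a1 by 1.23 (SE 0.28). Of 18 genes of glycolysis and glycogen 4 rose, with a median of 0.35 (camera adjusted p = 0.0322, and 0.754 with an estimated correlation). T and B lymphocyte genes had a median of 0.74 (camera adjusted p = 0.0322, and 0.449 with an estimated correlation), and 2 of 8 rose, the receptor gene Cd28 by 1.32 (SE 0.29) and Cd37 by 1.57 (SE 0.45). Without replicate 3 of mdx at day 7 the oxidative phosphorylation and glycolysis lists had an adjusted p of 0.192 and the lymphocyte list 0.183. Without replicates 2 and 3 of mdx at day 14 the glycolysis list had 0.151 and 0.113, and without replicate 1 the lymphocyte list had 0.0568.

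Other falls in mdx included H1f10 (-3.54, SE 0.28), the Wnt receptor Fzd2 (-3.19, SE 0.44), Plekho1 (-3.02, SE 0.24), Col18a1 (-2.98, SE 0.25, with another of its probe sets at 0.18), Wnt4 (-2.89, SE 0.24), the receptor kinase Fgfr4 (-2.79, SE 0.23), Commd5 (-2.79, SE 0.27), Ccdc86 (-2.68, SE 0.34) and Ppp2r5d (-2.66, SE 0.25). On the day 23 control array Wnt4 read 1641, Plekho1 1715 and Ppp2r5d 1183, against 1508, 1901 and 1255 in control at day 7 and 127, 171 and 154 in control at day 14. With 1 probe set per gene the largest rises were in Meg3 (4.81, with its other probe set at -1.51), Adh7 (2.56), Ctsb (2.48, with 3 other probe sets from -0.04 to 0.37), H2-T18 (2.40), Sac3d1 (2.39, with its other probe set at -0.09), the sulphotransferase Chst3 (2.24), Prss29 (2.23), Agap1 (2.22, with its other probe set at 0.34), Ckm, muscle creatine kinase (2.19, with its other probe set at 0.18), and S100a14 (2.15). These probe sets of Meg3 and H2-T18 read 7733 and 2085 on the day 23 control array, against 882 and 968 in control at day 7. Adh7, Ctsb, Chst3 and Prss29 read 784, 320, 211 and 126, near their day 7 control means of 720, 338, 209 and 108. Sac3d1, Agap1, Ckm and S100a14 read 67.9, 512, 350 and 1921, below their day 7 control means of 232, 709, 412 and 2944.

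In mdx 1908 of 7140 probe sets passed, 896 higher and 1012 lower at day 14. With each array scaled to the same median 747 were higher and 1460 lower, with a shift of -0.12 in the median of all probe sets, and without replicate 1 of mdx at day 7 the count was 1007. The calls shared with control numbered 719 among the higher, where independent calls give 188, and 880 among the lower, where they give 270, with 3 calls in opposite directions. The log2 differences of the genotypes correlated at r = 0.827 across probe sets, which are not independent replicates. A technical difference shared by the day 14 arrays of both genotypes would also give such sharing and such a correlation. Neither therefore tells a change with age from a technical difference. Dmd differed between the ages by -0.05 (SE 0.30, adjusted p = 0.904) in control, a value that was 0.16 with the values as deposited and 0.31 without replicate 2 of control at day 14, and by -0.79 (SE 0.30, adjusted p = 0.0658) in mdx. Of the mdx calls 694 had a day 23 control value at least 50% of the way from day 7 to day 14, and without the 3 arrays on which some of the brightest probe sets read low 886 probe sets passed.

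The single day 23 control array has no replicate check. Against the day 7 control mean, embryonic and neonatal isoforms had a median log2 difference of -1.02, imprinted growth genes -0.96, extracellular matrix genes -0.84, cell cycle genes -1.17 and neutrophil and marrow genes -3.14, each at percentile 0 among random lists. Adult fast fibre genes were at 0.68 and glycolysis and glycogen genes at 0.64, each at percentile 100, and oxidative phosphorylation genes were at 0.27, at percentile 99.8. Against the day 14 control mean, slow fibre genes stood at 0.78, at percentile 100, and neutrophil and marrow genes at -1.21, at percentile 0.22.

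Among probe sets above 1815, the 75th percentile of all values, at day 14 or day 23, the largest rises from day 14 to day 23 were in the chaperone gene Dnajb5 (log2 difference 3.93), the methyltransferase gene Smyd2 (3.65), Hipk2 (3.47), Ruvbl1 (3.45) and Abcf2 (3.25). Smyd2 read 2419 in control at day 7, 234 ± 29.2 at day 14 and 3631 at day 23. The largest falls among them were in Prp2 (-3.73), Usf1 (-3.46), Usp15 (-3.33), Psapl1 (-3.31) and Crb3 (-3.09).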

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

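The spike-in and antisense control comparisons were chosen only after the result was seen. So were the comparison of calls with the day 23 array as the whole cause, the day 14 marrow median and all counts over other splits of the arrays. The same holds for the use of a bootstrap interval in the test on other probe sets of a gene. The rest of that test and the test on marrow and bone scores were written down before their results were seen.

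A difference between the mdx effects at day 14 and day 7, tested by the difference itself, singled out 1 probe set and 6 gene lists. With an estimated correlation 0 of 26 lists passed, where the smallest adjusted p was 0.445. Snx17 differed by 2.17, with its other probe set at -0.495. The lists had median log2 differences of 2.33 for neutrophil and marrow genes, 0.70 for bone and cartilage genes, 0.42 for macrophage and myeloid genes, -0.61 for adipocyte genes, -0.43 for nerve and Schwann cell genes and -0.12 for oxidative phosphorylation genes. Over 100 splits of the arrays within age, 16 gave at least as many probe sets as the real 1, with a highest count of 2 among the others, so chance is not excluded for that count. For the lists the splits were not counted.

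The day 14 arrays stood apart from both the day 7 arrays and the day 23 array, so part of the age differences may be technical. On the first principal component the day 14 control arrays, at 32.1 to 62.6, also lay apart from the day 14 mdx arrays, at 20.7 to 24.6. Their mean log2 spike-in signals overlapped, at 12.85 to 13.25 in control and 12.55 to 12.90 in mdx. Part of the mdx differences at day 14, and of their difference from day 7, may therefore be technical too, which was not tested. The spike-in signal was higher on the day 14 arrays by 0.66 on the log2 scale (exact two-sided permutation p = 0.00216, the smallest that 924 splits allow), and the day 23 array lay nearer the day 7 mean. The 15 antisense control probe sets also read higher on the day 14 arrays, by 0.81 (exact two-sided permutation p = 0.00216). On them the day 23 array, at 8.29, lay below the day 7 mean of 8.61. Among calls in mdx, 65.46% of other probe sets of the gene shared the direction for calls kept at day 23. For calls not kept the share was 52.41%, a difference of -13.05 percentage points (95% bootstrap interval -21.4 to -4.75). Of all tested probe sets, 50.29% lay in the direction of the calls kept and 49.95% in that of the calls not kept. For calls not kept, other probe sets thus agreed little more often than tested probe sets in general. Probe-set-specific readings on the day 14 arrays could give such a pattern. Calls kept at day 23 outnumbered calls that went beyond the criterion in the opposite direction 4.13 to 1, past the ratio of 2 set as the bound against a technical difference as the whole cause. A condition added after that ratio was seen asks for more than 1 day 23 array, since a single array excludes nothing, so that cause and a change with age cannot be told apart, and growth of the muscle, not tested apart from the arrays, stays open.

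Neutrophil and bone genes were lower in mdx at day 7, which may reflect different amounts of bone and marrow in the samples. The lists share 0 genes, and deviations of the marrow and bone scores from their group means correlated over the 12 arrays at r = 0.763 (permutation p = 0.0434, 0.0743 adjusted over 3 relations) and rho = 0.713 (permutation p = 0.0428), marrow and erythroid scores at r = 0.591 (p = 0.0495, 0.0743 adjusted) and bone and erythroid scores at r = 0.498 (p = 0.192), so 0 of the 3 relations passed when adjusted. Without the 2 arrays farthest from the median these were 0.527, 0.595 and 0.271, so the relation of marrow and bone rests in part on those arrays. An effect of mdx on these cells cannot be told apart from this, since the marrow median log2 difference of -0.0725 at day 14 neither repeats nor opposes the day 7 difference beyond the spread of its members. The labels do not describe the dissection, so no sort or gate that would remove such tissue is given in the sources used here.

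For each comparison of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. For mdx against control at day 7 the real split gave 0 probe sets and the highest other 0, so all 10 splits gave as many. At day 14 the real split gave 6 and the highest other 5, for day 14 against day 7 in control 3408 and 0, and in mdx 1908 and 1. In these last 3 comparisons 1 split, the real one, gave as many.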

How the results depend on the processing

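The alternatives that leave out the 3 arrays with low bright probe sets or require the day 23 array to lie at least 50% of the way were chosen after seeing the data; the others were planned. The count of 0 for mdx against control at day 7 was the same under every setting run other than leaving out 1 array, which gave 0 to 12. With an estimated correlation 2 lists passed at day 7, 0 for the difference of the mdx effects and 0 for each age comparison.

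For mdx against control at day 14 the count of 6 became 1 with 4 times the pseudocount, with no filter, with an adjusted p under 0.01 and without the 3 arrays, where 2 lists passed. It became 2 with each array scaled to the same median and with the values as deposited, 12 without a variance trend, 3 with 1 probe set per gene and 0 with only the arrays compared. Leaving out 1 array gave 1 to 56. For the difference of the mdx effects the count of 1 became 2 without a trend, 0 with 1 probe set per gene and 0 without the 3 arrays, and ranged over 0 to 16 leaving out 1 array. Its 6 lists became 2 with each array scaled to the same median and 1 to 9 leaving out 1 array.

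For day 14 against day 7 in control the 3408 calls became 1904 with the strict filter, which tests fewer probe sets, 2090 at an adjusted p under 0.01, 1732 with a fold change of at least 2 and 1087 with the day 23 criterion. In mdx the 1908 became 783, 768 and 694 under the last 3 of these, 886 without the 3 arrays and 1007 to 1513 leaving out 1 array, with 4 to 8 lists. The difference in Dmd with age in control reversed to 0.16 with the values as deposited, and leaving out 1 array gave -0.28 to 0.31. Replicates shared only a number, since same-number deviations correlated at -0.146 to 0.0817 between the day 14 groups, where other pairs reached 0.165. With a replicate block the day 14 count was 1 and that of the difference 0. Stricter thresholds, the strict filter and the day 23 criterion lower a count by construction; for the other changes the cause was not tested.

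Counting each gene named in a comparison once per setting, mdx effects at day 14 kept direction and call in 74, were weaker in 13 and reversed in 1 under other settings, and leaving out 1 array in 46, 9 and 4, with 1 stronger. Of the 10 genes counted, Dmd, Dag1, Cav3, C1qc, Col3a1 and S100a8 had not passed, and count as kept while they stay uncalled. The weaker values therefore all belong to Myh3, Snx17, Psmd10 and Erdr1, so these calls were less stable than the totals show. C1qc reversed to 0.0926 with each array scaled to the same median, a scaling that moved the day 14 median of all probe sets to 0.135 from 0.0545. Leaving out 1 array, C1qc had -0.16 to 0.10 and S100a8 had -0.60 to 0.65. At day 7, where 0 probe sets had passed, 0 reversed. For the difference of the mdx effects, where Snx17 alone had passed, 0 reversed and 1 was weaker under other settings and 1 leaving out 1 array. With age in control 371 kept them, 4 were weaker and 1, Dmd, reversed under other settings, and 251, 6 and 1, again Dmd, leaving out 1 array. In mdx 405 kept them, 5 were weaker and 4 stronger, and leaving out 1 array 269 kept them and 17 were weaker. Of 104 list medians for day 23 against day 14, 34 moved under other settings, of 104 against day 7 39 moved and 1, complement, reversed from -0.10 to 0.00875 with each array scaled to the same median, and of 40 values of named genes 15 moved. Dim probe sets limit the fit, with a median SD of 0.333 on the log2 scale in the lower 50% by brightness and 0.238 in the brightest 5%.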

Other observations

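The test on other probe sets of a gene was written before its result was seen, its pattern was reworded afterwards from many to some of the brightest probe sets, and the averaged mdx effect was chosen after seeing the data.

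Averaged over the 2 ages, an mdx effect chosen after the data were seen passed for 3 of 7140 probe sets in limma, with 623 at an unadjusted p under 0.05. Erdr1 differed by -1.98 (SE 0.24, adjusted p = 0.0112), with its other probe set at -0.05 at day 7 and -0.78 at day 14, and a probe set without a gene symbol by -0.83 (adjusted p = 0.0196), while Snx17 differed by 0.96 (adjusted p = 0.0112), an average of -0.12 at day 7 and 2.05 at day 14, with its other probe set at 0.05 and -0.44. The mdx effects at the ages correlated at r = -0.036 across probe sets, which are not independent replicates.

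Some of the brightest probe sets read at least 4-fold low on 3 arrays: 9 of 364 on replicate 2 of control at day 7, 5 of 355 on replicate 3 of mdx at day 7 and 25 of 360 on replicate 1 of mdx at day 14. Replicate 2 of control at day 14 also had 5 of 353 and was not among the 3 arrays left out together. The 3 arrays had maximum deposited values of 27195, 27277 and 33542, and the largest maximum was 92213. Replicate 1 of control and of mdx at day 7 had 32218 and 32456, with 0 of 351 and 0 of 356 counted as low. A reading was counted only where the other arrays of its group were bright on average, so a probe set low on several of them can be missed. Gnas, for example, read 1819, 372 and 22351 on the day 7 control arrays. Control probe sets were outside this count. On replicate 1 of control at day 7 the ratio of the 3' to the 5' Gapdh control value was 0.0204. For 14 low readings with another probe set of the gene, the median deviation was -3.25 and that of the other probe sets -0.67, with 35.7% of them lower by more than 1. A fault of single probe sets and less of the transcripts cannot be told apart from these values, since they fall between the bounds set for either.

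Xist, expressed from the inactive X chromosome, had deposited values of 21.3 to 228 over the 13 arrays, and the Y-linked Eif2s3y 948 to 1952. The Y-linked Kdm5d and Uty, which did not pass the filter, read 94.6 to 531 and 160 to 719.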
